A study of Caenorhabditis elegans with 2 samples.

How the data were processed

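The samples were whole hermaphrodite Caenorhabditis elegans of strain OP195 at the L4 larval stage, collected 56 hours after starved L1 larvae had been synchronised. The strain carries RBR-2 with a GFP-FLAG tag at its C terminus. RBR-2 is the worm member of the KDM5 family of histone H3 lysine 4 demethylases. Chromatin was sheared by sonication and immunoprecipitated, and the recovered DNA was sequenced (ChIP-seq). The labels disagree on the antibody: the description names one against GFP, and the antibody field gives rbr-2. Which was used, and so whether untagged RBR-2 could add to the signal, is not settled here. The labels gave 1 group, RBR-2-GFP at L4, with 2 biological replicates. They gave no second stage, genotype or treatment, so no groups were compared.

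The authors deposited 4 kinds of list for each of the genome builds ce11 and ce10: 1 list for each replicate, 1 list for the pooled replicates, and 1 optimal list that had passed the irreproducible discovery rate (IDR) procedure. Per the text deposited with the files, each replicate list was called from that replicate's alignment with a control, the pooled list was called from both alignments with a control, and the optimal list was derived from the replicate and pooled lists. The replicate and pooled lists held peaks together with background regions. The aligner, the peak caller, their versions and the IDR threshold were not given in the sources used here. The control reads were not analysed here. In every list the deposited signal value is the caller's own strength of a peak, and it was used only to rank and describe regions within a list. The deposited −log10 q-value column reached a ceiling of 2.92 in the optimal list, where all 3442 peaks had that value, so it ranked nothing. Peak lists give no read counts, so the depth of each library is unknown, and the precision of a single signal value could not be calculated.

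Regions were ranked by signal within their list. The optimal ce11 list was found to be identical to the 3442 regions with the highest signal in the pooled list. To compare replicates, the 3442 strongest regions were taken from each replicate list. Summits within 200 bp of each other were counted as shared. Positions are 1-based in ce11. Genes came from the Ensembl release 115 annotation of the same assembly, with 19973 protein-coding genes on the nuclear chromosomes, and the sequence and the tRNA pseudogenes came from RefSeq. The 5′ end of a gene was its annotated start. A gene was called bound when a peak summit lay within 500 bp of its 5′ end, so 1 peak between divergent genes counted for both. Peaks over 500 bp from every protein-coding 5′ end are called distal. Short RNA genes were tRNA, snRNA, snoRNA and rRNA genes, with a window of 200 bp on either side. Mitochondrial peaks were left out of every analysis of genes and sequence.

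Shares of peaks near a feature were tested against 1000 circular shifts of all summits within their chromosomes, with a two-sided p whose smallest possible value is 0.001. Signal medians, correlations across peaks and GC differences were tested with 100000 two-sided permutations, whose smallest p is 1e-05. GC content was compared between 200 bp around the summit and flanks 500 to 700 bp away. Bound genes were compared between chromosomes and between gene lists with two-sided Fisher exact tests, with Benjamini-Hochberg adjustment over the 29 lists and a threshold of 0.05. The background for the lists was all nuclear protein-coding genes. Intervals on shares are exact Clopper-Pearson 95% intervals and cover counting error only. They carry no error between animals or cultures, because genes and peaks are not replicates. With 2 replicates, values in each replicate's own strongest regions are given in place of a test of the spread between them.

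The main tests, gene lists, named genes and alternative settings were fixed before the data were examined. Shares by annotation class, by class of short RNA gene and of distal peaks on X were not part of that plan. The named genes were the nearest genes of the 20 strongest peaks within 500 bp of a 5′ end, up to 4 bound members with the highest signal in each list, all members of the list of H3K4 methylation enzymes and their complex subunits, rbr-2 and unc-119, and the 3 strongest distal peaks. The name daf-21 in the chaperone list matched no gene in the annotation. The alternatives were the stronger 50% of the optimal list, each replicate alone, windows of 250 and 1000 bp, assignment to the nearest gene only, the 5′ ends of all transcripts, a background of genes that had any pooled region in the window, and other distances for shared summits. Matching the builds by signal within 1% was added after the data were seen.

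The procedures were tested on simulated data with the real annotation. With 3000 peaks, some of them placed at 5′ ends, the measured share near 5′ ends averaged 43.1%, against 43.1% expected, and passed the threshold in 20 of 20 runs, compared with 1 of 20 runs for randomly placed peaks. The expected share was calculated from the placed share and the random runs, so the match checks only the counting. Simulated peaks were not clustered, and fewer shifts were used than for the data. Lists with odds raised 4-fold were called in 80 of 100 draws, and 3 of 1060 lists with unchanged odds were called. The raised lists had 32 to 79 members, so the first rate does not cover smaller lists. Lowered odds were not simulated. Genes were drawn independently, unlike divergent neighbours that share a peak. The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.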

Results

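Binding of GFP-tagged RBR-2 was mapped by ChIP-seq in whole L4 hermaphrodites, in 2 biological replicates of 1 group. The antibody is given as anti-GFP in one label and as rbr-2 in another, so signal from untagged RBR-2 cannot be excluded. The optimal list held 3442 peaks, of which 3423 lay on the nuclear chromosomes and 19 on the mitochondrial genome. Peaks had a median length of 440 bp (range 110 to 1297 bp), and nuclear peaks covered 1287 kb of 100.3 Mb. The deposited signal ranged from 65.2 to 4664 with a median of 114. The replicate lists from which these peaks derive held 26742 regions in replicate 1 and 28724 in replicate 2, background included, and the pooled list held 30000.

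The question of the first comparison was whether both replicates found the same sites. Of the 3442 strongest regions of replicate 1, 2735 (79.5%) had a summit within 200 bp of one of the 3442 strongest of replicate 2, and 2744 (79.7%) did so in the opposite direction. Shifted positions shared 56.7 ± 7.25 regions (SD over 1000 shifts, permutation p = 0.001, the smallest the shifts can give). A region in both replicate lists was found for 3415 optimal peaks (99.2%), and 2638 (76.6%) were among the strongest 3442 of both. The optimal list was derived from the replicate and pooled lists, so these shares are not an independent test of agreement. Across those 3415 peaks, the log2 signals of the replicates had a Pearson r of 0.827 and the signals a Spearman rho of 0.781 (permutation p = 1e-05 for each, the smallest possible). These correlations run across peaks, which are not independent replicates and were selected from the same data.

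**Figure D1:**
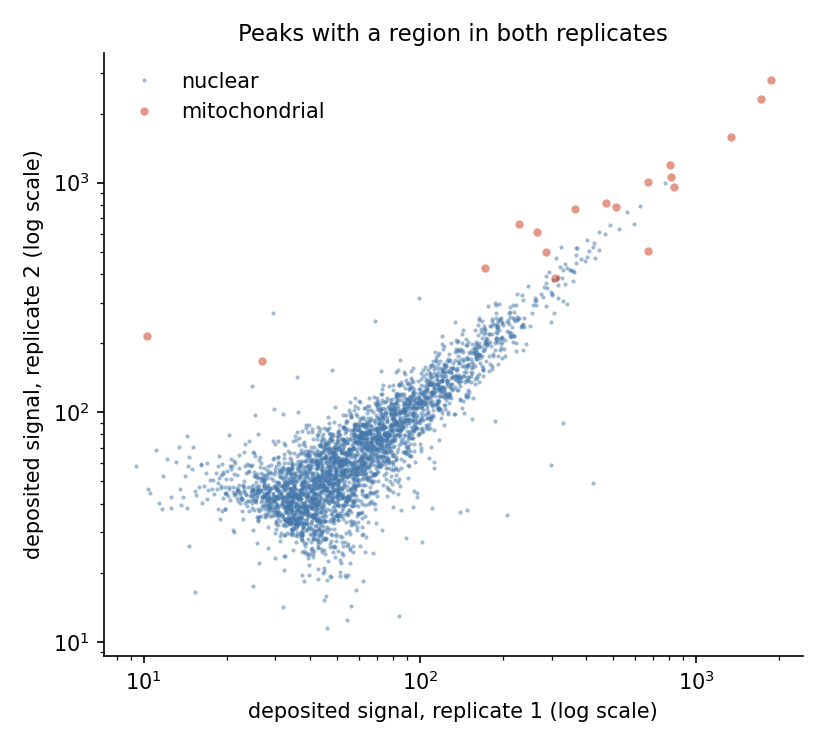
Deposited signal of the 3415 optimal peaks with a region in both replicates, replicate 1 on the horizontal and replicate 2 on the vertical axis, both on log scales. Each point is a peak, with nuclear peaks small and blue and mitochondrial peaks large and red; the Spearman rho is 0.781.

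The second question was where RBR-2-GFP lay relative to genes. Peaks collected just upstream of protein-coding genes: 1513 of 3423 nuclear summits (44.2%) were within 500 bp of a 5′ end, against 18.4% ± 0.666 of shifted summits (SD over 1000 shifts, permutation p = 0.001). The share was 44.5% among the strongest regions of replicate 1 and 43.2% in replicate 2. Of the summits near a 5′ end, 1318 (87.1%) lay upstream of it, with a median position of −159 bp and quartiles at −260 and −65 bp. These distances are to annotated gene starts. The sites where transcription begins were not mapped here, so the distance of summits from them is not known. Among 25604 pooled regions that overlapped no optimal peak, 20.7% were as close to a 5′ end (odds ratio 3.04, Fisher exact p = 5.83e-181).

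**Figure D2:**
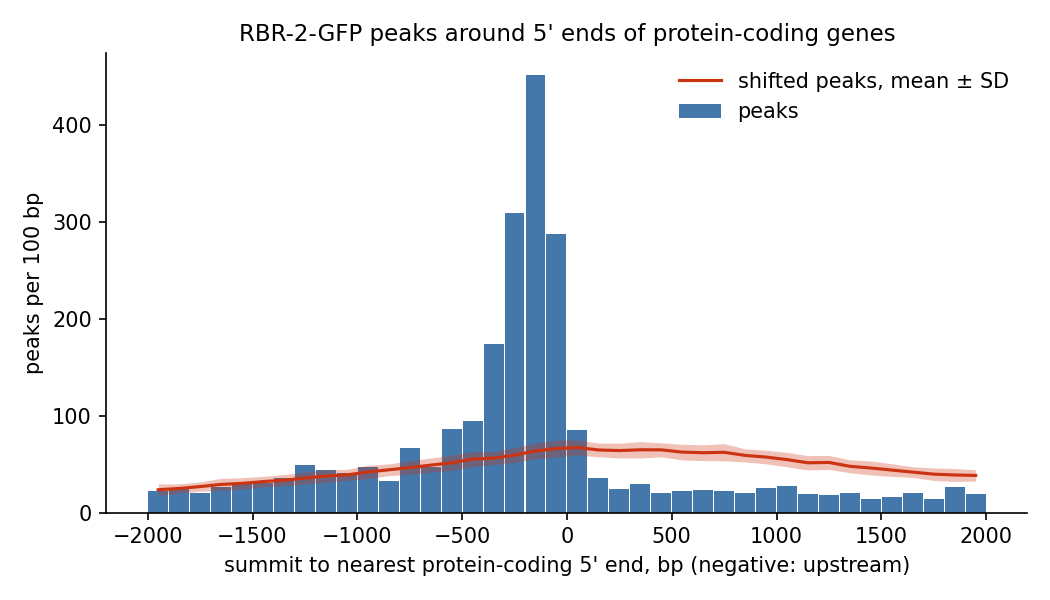
Number of nuclear peaks per 100 bp by the distance from the summit to the nearest protein-coding 5′ end, in bp, with negative values upstream. Bars are peaks, and the line with its band is the mean ± SD of shifted peaks; the excess lies upstream of the 5′ end, with a median of −159 bp for peaks within 500 bp.

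Summits were rare in coding sequence. Coding exons held 75 summits (2.19%), compared with 24.5% ± 0.790 after shifts, and introns held 21.5% compared with 34% ± 0.918. The share in 3′ UTRs was also below that of shifted summits (1.08% against 3.38%). Intergenic DNA held 2071 summits (60.5% against 32.9% ± 0.880), and 5′ UTRs held 3.77% against 1.42%. Each of these shares had a permutation p of 0.001 in the shift test, also after adjustment over 7 classes of annotation. The test by annotation class was not among those fixed before the data were examined.

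Peaks near 5′ ends had a median signal of 123, against 107 for the 1910 distal peaks, a ratio of 1.15 (permutation p = 1e-05). This order did not hold among strong peaks: in the stronger 50% of the optimal list the ratio was 0.947 (permutation p = 0.0489).

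Several of the 20 strongest peaks near a 5′ end lay at genes of protein synthesis, a theme that was not tested on this set. The strongest of the 20 was at rpl-3, encoding a protein of the large ribosomal subunit (chromosome III, 3867300 to 3867814, intergenic, signal 1765, summit 276 bp upstream). It ranked 7 in both replicates with mitochondrial regions counted. Peaks at rpl-15 (signal 1302), rpl-35 (1069), rps-1 (847), rpl-7A (633) and rpl-12 (628) were also among the 20, together with iff-2, a homolog of translation factor eIF5A (771), and drr-2, a homolog of eIF4H (681). The second strongest, at Y17G9B.5 (chromosome IV, 4749854 to 4750266, signal 1414), lay between this gene and rpl-20. Other genes on the list were cdc-48.1, encoding a protein-unfolding ATPase (signal 1154), cox-5A of cytochrome c oxidase (816), the histone gene his-37 (942), tasp-1 (1257), the Integrator subunit gene ints-4 (702) and hsr-9, a 53BP1 homolog (731). The remaining names were serp-1.1 (710), wip-1 (697), tos-1 (642), the Pumilio-family gene puf-9 (636) and trap-3 (631). All but the ints-4 summit, which was in the 5′ UTR, lay upstream of the named gene. At rps-1, puf-9 and trap-3 the summit was inside an annotated noncoding RNA. Another protein-coding 5′ end lay in the window of 7 of these peaks, so their target could not be assigned to a single gene.

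A further question was which genes carried RBR-2-GFP at their 5′ ends. In all, 1890 of 19973 protein-coding genes (9.46%, interval 9.06 to 9.88%) were bound. Among 29 gene lists, 14 held more bound members than other genes, 5 held fewer and 10 did not pass the test in either direction. Cytosolic ribosomal protein genes stood highest within 500 bp, with 63 of 79 bound (79.7%, interval 69.2 to 88.0%, odds ratio 38.9, Fisher exact adjusted p = 8.22e-49). Their share was 73.4% in the strongest regions of replicate 1 and 77.2% in replicate 2. This rank depended on the window: within 250 bp, 17 of 79 were bound (odds ratio 4.30), below translation factors (13 of 39, 7.83), proteasome (11 of 33, 7.82) and respiratory chain genes (15 of 51, 6.53), among others. With the nearest gene only, 38 were bound (odds ratio 11.8). The strongest members were rpl-3, rpl-20, rpl-15 and rpl-35.

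**Figure D3:**
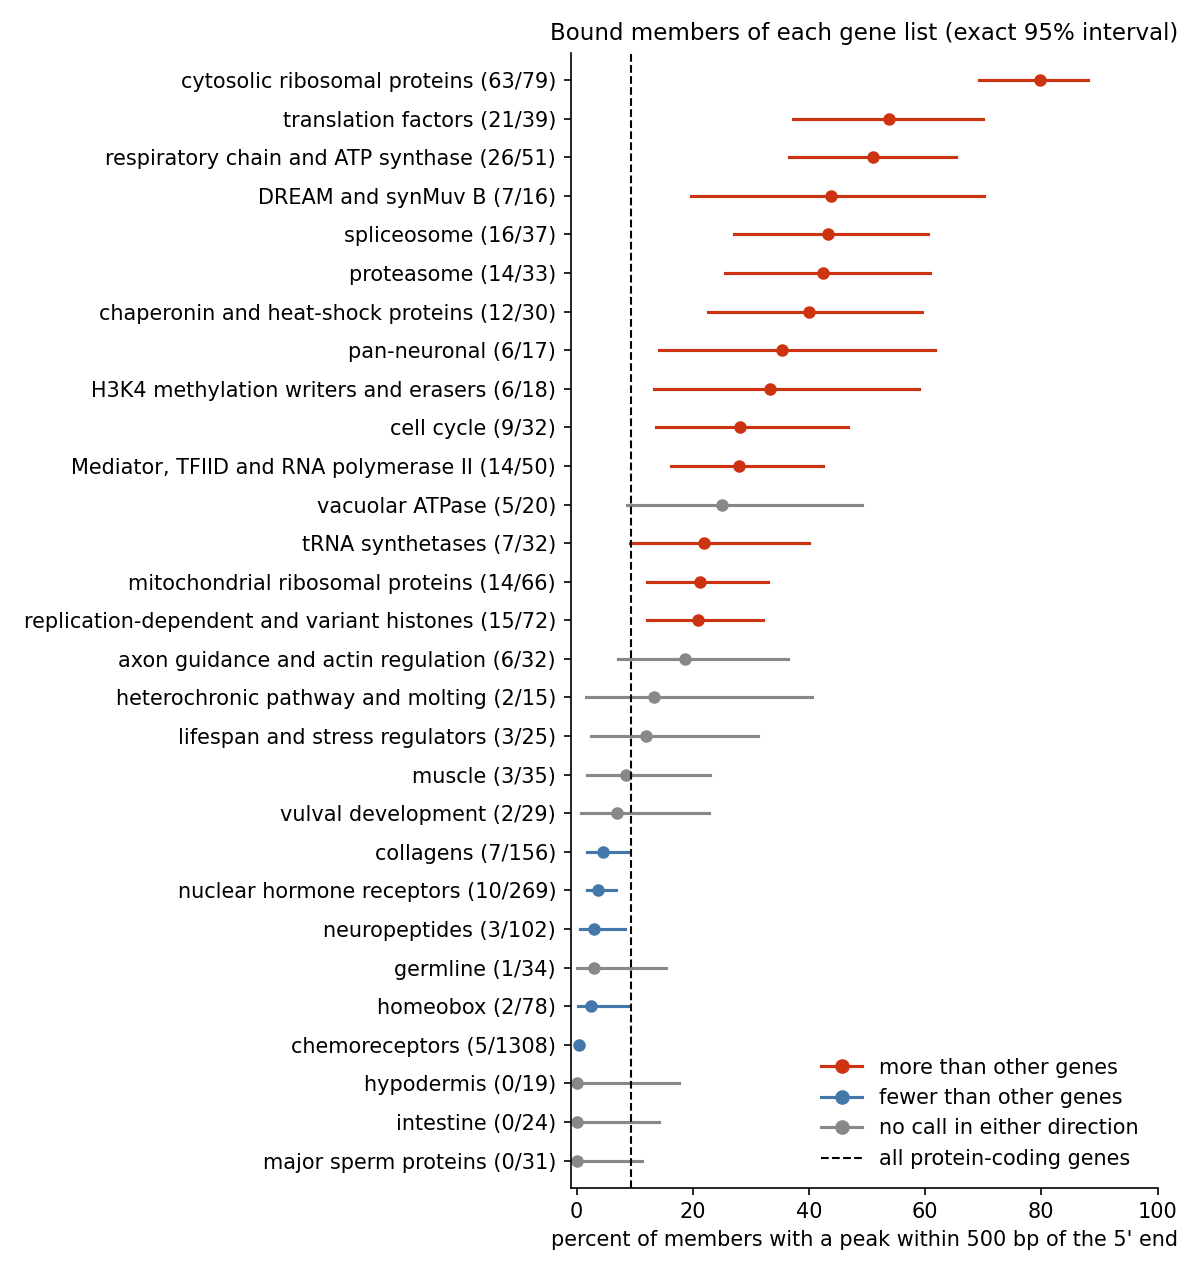
Percent of the members of each of 29 gene lists with a peak summit within 500 bp of the 5′ end, with exact Clopper-Pearson 95% intervals for counting error, and bound and total members beside each name. The dashed line is the share of all protein-coding genes (9.46%); cytosolic ribosomal proteins (79.7%) stand highest in this window but not within 250 bp, and colours mark lists called as having more or fewer bound members and lists with no call.

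Genes for translation factors, energy metabolism and protein turnover were also often bound. Of translation factor genes, 21 of 39 were bound (53.8%, odds ratio 11.3, Fisher exact adjusted p = 2.38e-11), led by iff-2 (signal 771), eef-1A.2 (419) and eif-3.C (396). Of genes for the respiratory chain and ATP synthase, 26 of 51 were bound (51%, odds ratio 10.1, exact adjusted p = 4.63e-13), including cox-5A (816), cox-5B (626), atp-1 (472) and cyc-1 (305). The spliceosome list had 16 of 37 (43.2%, exact adjusted p = 4.2e-07), with 1 peak of signal 357 between rsp-2 and rsp-1 counted for both. The proteasome list had 14 of 33 (42.4%, exact adjusted p = 3.08e-06), led by rpn-3 (400) and rpn-11 (286). Chaperonin and heat-shock genes had 12 of 30 (40%, exact adjusted p = 3.52e-05), led by hsp-1 (603), cct-8 (478) and hsp-3 (450). Mitochondrial ribosomal proteins had 14 of 66 (21.2%, exact adjusted p = 0.00925), led by mrpl-28 (278), and tRNA synthetases 7 of 32 (21.9%, exact adjusted p = 0.0451), led by ears-2 (298). The call for tRNA synthetases ended in either replicate alone (exact adjusted p = 0.093 without replicate 1 and 0.162 without replicate 2), in the stronger 50% of the optimal list (3 bound, 0.333) and within 250 bp (5 bound, 0.0807).

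Another 5 lists, of varied function, also held more bound members. Of the DREAM and synMuv B genes, which repress germline and cell cycle genes in somatic cells, 7 of 16 were bound (43.8%, odds ratio 7.47, Fisher exact adjusted p = 0.00115). The strongest were lin-54 (signal 628), lin-53 (395), lin-9 (355) and lin-35, the retinoblastoma homolog (329). The lin-54 peak was the one also assigned to rpl-12. Mediator, TFIID and RNA polymerase II genes had 14 of 50 bound (28.0%, exact adjusted p = 0.000566), led by rpb-11 (301) and taf-4 (240). Cell cycle genes had 9 of 32 (28.1%, exact adjusted p = 0.0059), led by pcn-1, encoding the replication clamp (443), and cdc-6 (230); this call ended within 250 bp (4 bound, exact adjusted p = 0.192). Histone genes had 15 of 72 (20.8%, exact adjusted p = 0.00785), led by his-37 (942); his-67 and his-68 shared a peak (272), and near-identical histone copies make single assignments uncertain. Pan-neuronal genes had 6 of 17 (35.3%, exact adjusted p = 0.00785), led by rgef-1 (250.6) and egl-21, a neuropeptide-processing enzyme gene (213).

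A list of enzymes that write or erase H3K4 methylation, the mark removed by KDM5 demethylases, and of subunits of their complexes was examined in full. Of 18 genes, 6 were bound (33.3%, interval 13.3 to 59.0%, odds ratio 4.80, Fisher exact adjusted p = 0.0094). They were set-16, an MLL-type methyltransferase gene (signal 681), ash-2 (282), utx-1 (123), set-2 (80.2), dpy-30 (80) and wdr-5.3 (69.3). The windows of set-2 and wdr-5.3 held a region in the strongest 3442 of replicate 1 but not of replicate 2. The weakest optimal peak had a signal of 65.2. The set-16 peak lay between that gene and drr-2. Of these 6, set-16 and set-2 encode H3K4 methyltransferases, ash-2, dpy-30 and wdr-5.3 encode complex subunits without that activity, and utx-1 encodes an H3K27 demethylase. Weaker pooled regions, outside the optimal list, lay in the windows of hcf-1 (signal 60.3), wdr-5.1 (50.7), set-17 (31.6), amx-1 (29.1), wdr-5.2 (20.6), spr-1 (17.5) and set-30 (14.9). The windows of rbr-2, spr-5, rbbp-5, cfp-1 and lsd-1 held no pooled region, although rbbp-5 had a region in the strongest 3442 of replicate 2 and lsd-1 in those of replicate 1. The call for this list ended when peaks were assigned to the nearest gene only (3 bound, exact adjusted p = 0.21), within 250 bp (3 bound, exact adjusted p = 0.16), in the stronger 50% of the optimal list (3 bound, 0.122) and against genes with any pooled region in their window (odds ratio 2.14, 0.317).

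Large families of receptor and cuticle genes were seldom bound. Chemoreceptor genes had 5 of 1308 bound (0.382%, interval 0.124 to 0.890%, odds ratio 0.0342, Fisher exact adjusted p = 7.97e-49), among them sri-5 (signal 268) and srh-16 (264). Only 61 of these genes had any pooled region in their window, background included. Against other genes with such a region the odds ratio was 0.221 (Fisher exact adjusted p = 0.000881). Why most chemoreceptor windows held no region was not tested. The tests count genes as independent draws, which neighbouring family members may not be. Nuclear hormone receptor genes had 10 of 269 (3.72%, exact adjusted p = 0.00139), led by nhr-47 (421) and nhr-1 (280). Neuropeptide genes had 3 of 102 (2.94%, exact adjusted p = 0.0313), namely flp-23 (93.8, with its summit inside a short RNA gene), nlp-4 (82.0) and nlp-24 (67.6). Collagen genes had 7 of 156 (4.49%, exact adjusted p = 0.0451), led by col-85 (250), whose summit was inside a short RNA gene. Homeobox genes had 2 of 78 (2.56%, exact adjusted p = 0.0486), ceh-38 (428) and ceh-39 (157). The calls for collagen and homeobox genes ended in either replicate alone, with exact adjusted p of 0.0571 and 0.0513 without replicate 2 and of 0.0781 and 0.0778 without replicate 1. Collagens had odds ratios of 0.447 in the optimal list, 0.450 without replicate 2 and 0.470 without replicate 1. For homeobox genes these were 0.251, 0.252 and 0.264. In the stronger 50% of the list both calls ended as well (collagens 0.229, odds ratio 0.466, and homeobox 0.514, odds ratio 0.467). The homeobox call also ended within 250 bp (exact adjusted p = 0.461), with the nearest gene only (0.193) and against genes with any pooled region (0.0564). The call for neuropeptides, with an odds ratio of 0.289 in the optimal list, ended in 3 settings. These were without replicate 1 (5 bound, odds ratio 0.517, exact adjusted p = 0.21), within 250 bp (2 bound, 0.309, 0.16) and with the nearest gene only (3 bound, 0.377, 0.151).

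The other 10 lists did not pass the test. No peak lay at the 5′ ends of 31 major sperm protein, 24 intestinal or 19 hypodermal genes, where the intervals reached 11.2%, 14.2% and 17.6%. Without replicate 2, 1 hypodermal gene was bound. Of the intestinal genes, 1 was bound within 1000 bp and 1 with the 5′ ends of all transcripts. Within 1000 bp the major sperm protein list was called as having fewer bound members (0 bound, exact adjusted p = 0.0381). Germline genes had 1 of 34 bound, nos-3 (signal 107), and muscle genes 3 of 35, unc-60 (227), unc-112 (157) and act-4 (143). Without replicate 1, 2 germline genes were bound (odds ratio 0.628, against 0.290 in the optimal list). Vulval development had 2 of 29, egl-17 (210), whose summit was inside a short RNA gene, and lin-7 (183). Axon guidance had 6 of 32, led by unc-76 (307) and unc-115 (295). The heterochronic list had 2 of 15, lin-14 (121) and mab-10 (118), and was called with the 5′ ends of all transcripts (6 bound, exact adjusted p = 0.00622) and within 1000 bp (5 bound, 0.0381). Lifespan regulators had 3 of 25, sir-2.1 (128), akt-1 (72.3) and daf-16 (70.7). The vacuolar ATPase list had 5 of 20 with an exact adjusted p of 0.0508, led by vha-8 (283), and was called without replicate 2 (7 bound, exact adjusted p = 0.00323), in the stronger 50% of the list (5 bound, 0.00884) and within 1000 bp (6 bound, 0.0381), but within 250 bp only 1 was bound (odds ratio 0.816, exact adjusted p = 1) and against genes with any pooled region the odds ratio was 1.2 (0.868). Whole animals were used, so binding confined to few cells would be diluted in the sample.

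The background used for the lists mattered for most of these calls. Against genes that had any pooled region in their window, 5 of the 14 lists with more bound members were still called, namely cytosolic ribosomal proteins, translation factors, spliceosome, respiratory chain and histones, and 4 of the 5 with fewer. Besides the H3K4 list, the calls ended for mitochondrial ribosomal proteins (odds ratio 1.09, exact adjusted p = 0.868), tRNA synthetases (1.2, 0.804), cell cycle genes (1.88, 0.237), pan-neuronal genes (2.50, 0.188), Mediator, TFIID and RNA polymerase II genes (1.95, 0.133), DREAM and synMuv B genes (2.92, 0.132), the proteasome (2.34, 0.0564) and chaperones (2.74, 0.0526). With the nearest gene only, the calls also ended for chaperones (4 bound, exact adjusted p = 0.351), histones (9 bound, 0.178), mitochondrial ribosomal proteins (9 bound, 0.116) and DREAM and synMuv B genes (4 bound, 0.0596). In the stronger 50% of the optimal list they also ended for cell cycle genes (4 bound, exact adjusted p = 0.142) and pan-neuronal genes (3 bound, 0.113). Cytosolic ribosomal proteins, translation factors, spliceosome, respiratory chain, nuclear hormone receptors and chemoreceptors kept their calls under each of the 8 alternatives that could change a list, but the size of the difference varied. The odds ratio ran from 4.30 (within 250 bp) to 45.4 (within 1000 bp) for ribosomal proteins, from 5.29 to 11.5 for translation factors, from 4.02 to 8.47 for the spliceosome and from 4.10 to 10.7 for the respiratory chain. It ran from 0.232 to 0.440 for nuclear hormone receptors and from 0.0221 to 0.221 for chemoreceptors.

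Binding was also compared between the X chromosome and the autosomes. At the 5′ ends of genes they did not differ by the test: 247 of 2731 X genes (9.04%, interval 7.99 to 10.2%) and 1643 of 17242 autosomal genes (9.53%, interval 9.09 to 9.98%) were bound, a ratio of 0.949 (Fisher exact p = 0.439). Among autosomes the share ran from 6.15% on V to 13.8% on I, with 13.3% on III. This ratio depended on the rules for genes: it was 1.15 (Fisher exact p = 0.0494) with the nearest gene only, and 0.889 (Fisher exact p = 0.0441) against genes with any pooled region in their window.

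Strong distal peaks, in contrast, were concentrated on X. X held 8 of the 10 strongest distal peaks, 25 of the 50 strongest and 447 of all 1910 (23.4%), whereas it held 0 of the 10 and 9 of the 50 strongest peaks near 5′ ends. Its share of the nuclear genome is 17.7%, and its share of distal pooled regions that overlapped no optimal peak was 20.1%. The 3 strongest distal peaks were all on X: an intergenic peak at 11093845 to 11094466 (signal 1155), a peak at 6296233 to 6296906 in an intron of mom-1 (1052), and an intergenic peak at 13700558 to 13701134 (974). They ranked 15, 19 and 21 in replicate 1 and 16, 18 and 22 in replicate 2. Of the 50 strongest distal regions, 23 were on X in replicate 1 and 24 in replicate 2. The sequence GCGCAGGG, searched after these positions had been seen, occurred within 200 bp of the summit in 12 of the 38 X peaks among the 100 strongest distal peaks. It was found in 11 of the 25 X peaks among the 50 strongest and in 1 of the 13 among the next 50, of which 4 were at a short RNA gene.

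**Figure D4:**
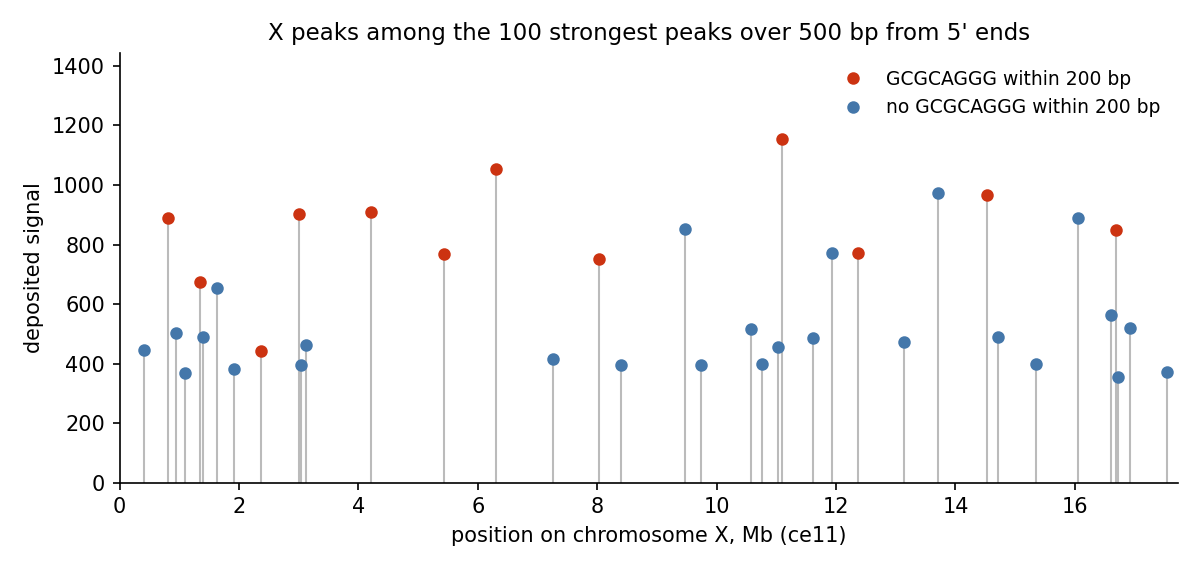
Position on chromosome X in Mb (ce11) and deposited signal of the 38 X peaks among the 100 strongest distal peaks of the optimal list. Each point is a peak, red where GCGCAGGG lies within 200 bp of the summit (12 peaks) and blue elsewhere; the strongest has a signal of 1155.

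Short RNA genes were a separate class of site. Of the nuclear summits, 374 (10.9%) lay within 200 bp of a tRNA, snRNA, snoRNA or rRNA gene, against 0.545% ± 0.131 of shifted summits (SD over 1000 shifts, permutation p = 0.001). The share was 10.7% in replicate 1 and 11.4% in replicate 2. Of 612 tRNA genes, 274 had a peak (44.8%, interval 40.8 to 48.8%), as did 90 of 346 snoRNA genes (26.0%) and 22 snRNA genes (17.1% of that class). None of 20 nuclear rRNA genes had a peak (interval up to 16.8%), nor did the 12 genes for spliced leader 1 RNA. Genes for spliced leader 2 RNA, which is joined to downstream messages of operons, had a peak at 8 of 18, with the highest signal at sls-2.1 (852), a gene named after its value was seen. The genes sls-2.1, sls-2.2 and sls-2.4 are annotated as snRNA genes, so they also count in that class. Copies of these RNA genes are often near-identical, so single genes are uncertain. How reads from such copies were placed is not known, so a gene without a peak may not be unbound.

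Peaks were richer in GC than their surroundings. The median GC content was 45.5% in 200 bp around the summit and 36.0% in the flanks, a difference of 9.5 percentage points (permutation p = 1e-05). Pooled regions that overlapped no optimal peak differed from their flanks by 3 points. Distal peaks differed by 12.3 points and peaks near 5′ ends by 5.25, and without peaks at short RNA genes by 12.5 and 4.75.

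The gene encoding the tagged protein was examined whatever its value. No region of the pooled list lay in rbr-2 (chromosome IV, 10920070 to 10926817) or within 20 kb of it, where random windows on that chromosome held a median of 12 regions and 4.5% held none. The interval without regions around it spanned 82.9 kb in the pooled list, 67.5 kb in replicate 1 and 82.2 kb in replicate 2. Such a gap was rare: 32 of 24634 gaps between pooled regions were at least as long, and the median gap was 1.32 kb. In the central parts of the chromosomes, where this gap lay, 5 of 8950 were. The labels describe transgenic worms that express the tagged protein, and the control reads were not analysed here. The cause of the gap was not tested, so the gap is not evidence that rbr-2 is unbound. At unc-119 (chromosome III, 10902641 to 10908935) 6 pooled regions lay in or beside the gene, the strongest with signal 108 at rank 1848, but its 5′ end was not bound.

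The optimal lists on the builds differed little. The ce10 list held 3445 peaks, of which 2797 (81.2%) had a ce11 peak of the same chromosome, rank and length, and 3439 (99.8%) one of the same chromosome and length with a signal within 1%.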

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

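The mitochondrial genome, which the analyses of genes did not use, held 19 optimal peaks in 13794 bp, or 1.38 peaks per kb compared with 0.0341 on the nuclear chromosomes. Their signal ranged from 269 to 4664 with a median of 1142, and 11 of the 19 strongest peaks of the whole list were mitochondrial. The replicate lists held 20 and 21 mitochondrial regions. No control library was analysed here, and no explanation was tested.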

How the results depend on the processing

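All alternatives below were planned except the matching of builds by signal, chosen after the data were seen, which raised the matched share from 81.2% to 99.8%. The top of the pooled list was identical to the optimal list, so that alternative tested nothing and is left out of the counts here. Of 50 alternative values of the main results, 39 kept their direction and their side of the threshold or stayed within 1.5-fold. Shares of peaks near 5′ ends (30.4 to 55.7%), shared summits (62.1 to 83.6%), replicate correlations (0.781 to 0.829), short RNA genes (10.7 to 13.5%) and GC differences (9 to 13 points) each kept their call. The ratio of near to distal signal turned to 0.947 (permutation p = 0.0489) in the stronger 50% of the list, and the X ratio to 1.15 with the nearest gene only, while it passed the threshold at 0.889 against genes with any pooled region. Lists with more bound members numbered 9 with the nearest gene only and 5 against genes with any pooled region. Lists with fewer numbered 3 in the stronger 50% of the list, within 250 bp and with the nearest gene only, and 2 to 3 without 1 replicate. Of the odds ratios of single lists, 190 of 231 alternatives gave the same call, 35 lost it, 6 gained one and 0 reversed. The cause was not tested. Unknown depth limits the reading of genes without a peak.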

Other observations

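Gene families outside the fixed lists also differed. Of 132 families defined by the letters of the gene name, with at least 10 members, 9 held more bound genes and 4 fewer (Fisher exact tests, Benjamini-Hochberg adjustment over the families, chosen after the data were seen). Nuclear pore genes (npp) had 11 of 26 bound (42.3%, exact adjusted p = 0.000469), led by npp-3 and npp-14. Vesicle sorting genes (vps) had 11 of 31 (35.5%, exact adjusted p = 0.00247) and secretory pathway genes (sec) 8 of 19 (42.1%, exact adjusted p = 0.00459), led by sec-61.B and sec-61.G. J-domain proteins (dnj) had 10 of 29, RNA-binding proteins (rbm) 6 of 13, ubiquitin-conjugating enzymes (ubc) 7 of 21 and cyclophilins (cyn) 6 of 16. The dhhc family had 6 of 14, and the unc genes, grouped by a mutant phenotype, 13 of 56. In contrast, F-box A genes (fbxa) had 0 of 170 bound (exact adjusted p = 1.17e-05), C-type lectins (clec) 3 of 240 (exact adjusted p = 1.22e-05), cytochrome P450 genes (cyp) 0 of 74 (exact adjusted p = 0.0161) and glucuronosyltransferases (ugt) 0 of 67 (exact adjusted p = 0.0256). Members of these families are often neighbours, so they are not independent draws.

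Several short sequences were more frequent at summits than in their flanks, at peaks near 5′ ends and at distal peaks alike. These counts and those by parts of chromosomes were chosen after the data were seen. Leaving out short RNA genes, ACGCGC or its reverse complement occurred within 100 bp around the summit at 18.6% of 1443 peaks near 5′ ends and at 0.970% of windows in their flanks (Fisher exact adjusted p = 1.33e-98 over 4160 comparisons). At 1606 distal peaks the leading sequence was GAGAGA, in 38% of centres and 5.76% of flanks (exact adjusted p = 1.1e-165), followed by AGAGAG (32.6% and 4.45%) and CGTCTC (24.7% and 2.74%). The same 3 were also more frequent in the centres of peaks near 5′ ends, GAGAGA in 22.7% against 5.3% of flanks (exact adjusted p = 1.51e-59), AGAGAG in 20.2% against 4.05% and CGTCTC in 19.1% against 3.64%. ACGCAG was found in the centres of 17.7% of near and 19.2% of distal peaks, and GACGCA in 19.2% and 17.6%. The classes were not tested against each other. Base composition was not held fixed in these comparisons. Centres held 47% GC and flanks 34.5% at the distal peaks, and 42% and 37.25% at those near 5′ ends. A higher share in centres may therefore partly reflect base composition. Some of these sequences overlap one another, so they are not separate observations. On V, genes in the middle of 3 equal parts of the chromosome were bound more often than genes in the outer parts (8.40% against 4.88%, odds ratio 1.79, Fisher exact adjusted p = 7.75e-06). On II the shares were 10.6% and 7.97% (exact adjusted p = 0.0294), and on I, III, IV and X no such difference passed the threshold. The mix of gene families in these parts was not held fixed, so position and gene family cannot be told apart here.

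Of the tests of explanations that follow, the one on tRNA genes with a sequence found once was chosen after its result was seen. The patterns themselves had been seen before the others were chosen. Peaks at tRNA genes were set against 3 explanations. Genes with a sequence found more than once in the genome had a peak more often (231 of 472, 48.9%) than genes with a sequence found once (43 of 140, 30.7%, Fisher exact p = 0.000151), so shared reads may add to the pattern, although the most used tRNA genes may also be the repeated ones. Genes with a sequence found once still had a peak in 30.7% of cases, against at most 5.00% after shifts. This does not decide whether shared reads are the cause. Only identical full-length sequences counted as copies, so near-identical genes could still share reads. A summit within 200 bp could also belong to a neighbouring tRNA gene. Proximity to protein-coding genes was argued against, since 190 of 421 tRNA genes over 1000 bp from any such 5′ end had a peak (45.1%, at most 4.04% after shifts). For tRNA-like sequence alone, tRNA pseudogenes had a peak less often, 5 of 209 (2.39%), than all tRNA genes (44.8%, Fisher exact p = 8.22e-37). How far pseudogene sequences differ from those of genes was not measured, and copy number was not matched. This comparison therefore does not decide whether sequence alone is the cause. Whether an untagged strain shows the same sites was not analysed here, and no biological explanation was tested.

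The pooled housekeeping lists, from ribosomal proteins to Mediator, had 192 of 437 genes bound (43.9%), against 8.69% of other genes (odds ratio 8.23). Stratified by GC content at the 5′ end, the Mantel-Haenszel odds ratio was 7.78 (interval 6.38 to 9.50), and stratified by the number of neighbouring 5′ ends it was 6.24 (interval 5.11 to 7.63). Both values argue against GC content and gene density as the whole cause. Strong transcription or open chromatin at these genes, which could attract signal for many tagged proteins, remains open, because no expression data, control library or second protein was analysed here.

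The concentration of strong distal peaks on X is the pattern most open to follow-up. Higher background on X was argued against as the whole cause. X held 20.1% (interval 19.5 to 20.6%) of 20311 distal pooled regions that overlapped no optimal peak. It held 50% of the 50 strongest distal peaks (interval 35.5 to 64.5%). The 20.1% was itself above the 17.7% of the nuclear genome that lies on X. The dosage compensation complex of C. elegans is loaded on X at recruitment sites, for which GCGCAGGG was taken as the core sequence. Only exact matches on either strand were counted, so a recruitment site with a variant of the core would count as lacking it. This core lay within 200 bp of the summit in 12 of the 38 strong X distal peaks (31.6%, interval 17.5 to 48.7%) and in 1 of the 100 strongest autosomal distal peaks (Fisher exact p = 4.68e-07), and in 0 of 76 windows 1000 bp away from the same X summits. These values are consistent with the hypothesis that part of the strong distal sites are such recruitment sites, but 26 of the 38 lacked the core, 4 of them at short RNA genes, and a general pull-down of accessible or highly occupied sites was not tested, whichever antibody was used.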
